A study of Macaca mulatta with 8 samples.

How the data were processed

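Total RNA of pools of 4 metaphase II oocytes was purified and taken through 2 rounds of amplification to biotin-labelled cRNA, per the labels' protocols, and hybridised to a single-colour Affymetrix array of the rhesus macaque. The deposited intensity values are MAS5 signals on a linear scale, per the submitters' processing notes, which give no version of that program. The mean of each array without its lowest and highest 2% of values was 150, as global scaling to a common target leaves it. MAS5 summarises each probe set by itself after subtracting background, so dim probe sets vary strongly between arrays. Amplification from the 3' end favours the ends of transcripts, and a probe set far from the end can lose signal on a poorly amplified array. Detection calls were not used here.

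The table held 52865 probe sets. The 99 control probe sets were left out of the tests, which left 52766. Of these, 24956 had 1 gene symbol, 361 had several and 27449 had none listed in the platform annotation. Entrez identifiers of 24616 probe sets with 1 symbol were found in the RefSeq table of the T2T-MMU8v2.0 assembly, and 0 symbols changed. Symbols that are only LOC numbers (1691 probe sets) were not used as names, which left 23265 named probe sets for 12993 genes. No gene was named from a probe set with several symbols, and a probe set without a symbol is unnamed here, not without a gene. No coordinates are given.

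Samples were grouped by their labels, 4 arrays per group. Values were taken as log2(signal + 8.2), where 8.2 is the 25th percentile of all non-control signals. A fold change on this scale understates the change of dim transcripts. Probe sets above the 50th percentile of the mean over all 8 arrays were tested (26383 probe sets, 15135 with a gene name, 9578 genes). The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, in vitro minus in vivo, and Benjamini-Hochberg adjustment at 0.05. Background on an array was the 95th percentile of 59 control probe sets for bacterial transcripts and tags that were not spiked in, whose signals ran from 0.2 to 52.7. Where all 4 arrays of a group lay at or below background, the fold was given as a bound, from the brighter group's mean log2 value and the dimmer group's mean with each array at the higher of its background and its signal.

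The rules and gene lists were written before the data were examined. Named genes are, per direction, the 15 with the largest log2 fold change among probe sets past the adjusted threshold whose groups do not overlap, filled up to 10 with probe sets of smallest unadjusted p and at least a 2-fold difference. If several probe sets of a gene qualified, the one with the smallest p was taken. To these were added up to 4 members of each gene list with the smallest unadjusted p, and 14 genes chosen for their role in the oocyte. The 25 lists covered oocyte-enriched genes, markers of granulosa, blood and stromal cells, meiosis, the spindle, mRNA storage, stress responses, metabolism, chromatin, imprinting, apoptosis, ribosomal proteins, protein turnover, DNA repair, signalling, adhesion, transport, early embryo factors and histones. Lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with the brightest probe set of each gene.

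Spread within groups, separation of groups and ratios of control transcripts were compared by exact permutation tests over 70 assignments or 35 splits of the arrays. The limma fit and camera were tested on simulated data built from the means and spreads of the real probe sets. Of 50 simulated probe sets changed 2-fold among 26383, 16.0% were recovered, and 72.0% were recovered at 4-fold, 94.0% at 8-fold and 98.0% at 16-fold, with 7 false calls among 147. With every member of a list shifted by 0.5 on the log2 scale among 9578 genes with independent noise, camera recovered 24 of 24 lists. The alternatives tried were other pseudocounts (1 and 27.7, the median signal), no filter and an upper-quarter filter, quantile normalization, median centring, other variance models, array weights, a replicate block, other set tests, and each array left out in turn. Control-transcript ratios as covariates were added after seeing the data.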

Results

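Transcript levels were measured in metaphase II oocytes of the rhesus macaque, the stage at which a mature egg waits for fertilization. A group of 4 arrays held oocytes that had matured in the animal, and a group of 4 arrays held oocytes that had matured in culture. Each array carried amplified RNA of a pool of 4 oocytes. The labels call the arrays of a group biological replicates, without saying which animals gave the oocytes, so p-values measure the spread between these pools. All 8 arrays had a 2% trimmed mean signal of about 150, and between 49.9% and 60.9% of the probe sets on an array lay above its background. The number of arrays limits the precision of every comparison.

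The comparison asked which transcripts differ between oocytes matured in culture and oocytes matured in the animal. Transcripts of INHBA, which encodes the inhibin and activin beta A subunit, were 8.46-fold higher in the pools matured in culture. Their signal was 165 ± 72.4 in vivo and 1483 ± 751 in vitro (SD, n = 4 each; limma adjusted p = 0.00226). A second INHBA probe set rose too, by 3.18 ± 0.39 (SE) on the log2 scale. STAR, whose product carries cholesterol into mitochondria for steroid synthesis, rose from 191 ± 98.9 to 1181 ± 490. STC1, encoding the secreted glycoprotein stanniocalcin, rose from 123 ± 35.7 to 649 ± 235. In the other direction, MRAP2, which encodes an accessory protein of melanocortin receptors, fell from 423 ± 215 to 15.8 ± 11.5.

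The imprinted noncoding RNA H19 was among the brightest transcripts that rose, from 2449 ± 407 to 11114 ± 4047 (log2 fold change 2.13 ± 0.22 SE, limma adjusted p = 0.000606). Another of its 3 probe sets also passed, at 293 ± 96.6 in vivo and 1184 ± 332 in vitro, and the remaining one had a log2 fold change of 1.10 at a limma adjusted p of 0.402. MT2A, a metallothionein that binds zinc and copper, rose from 3552 ± 1199 to 10512 ± 2377. DUSP1, a phosphatase that inactivates MAP kinases, rose 3.53-fold. The bradykinin receptor gene BDKRB1 rose 8.91-fold, the neuronal pentraxin gene NPTX2 rose 3.53-fold, and the potassium channel gene KCNK3 rose 2.78-fold. CTCFL, a germ-line relative of the insulator protein CTCF, rose 7.91-fold from a low signal of 35.3 ± 32.8, and its log2 fold change of 2.98 became 2.39 without in vivo replicate 2. PLAGL1, an imprinted zinc finger gene, rose 3.53-fold from 19.4 ± 6.18. LARGE2, encoding a glycosyltransferase, rose 5.23-fold. TMEM26 rose 8.55-fold at 1 probe set, while its other tested probe set had a log2 fold change of 0.07. A probe set each of MPPE1 and CYP3A5 was not above background on any in vivo array, which leaves a bound. At these probe sets MPPE1 was at least 3.74-fold higher and CYP3A5 at least 2.65-fold higher in the pools matured in culture. The other MPPE1 probe set was too dim to be tested, at 24.2 ± 23.1 in vivo and 28.6 ± 17.4 in vitro. The 2 others of CYP3A5 had log2 fold changes of 1.70 and 1.73 and did not pass (limma adjusted p = 0.214 and 0.132). They were at 13.4 ± 8.47 and 12.7 ± 8.91 in vivo, above background on at most 1 in vivo array and on all 4 in vitro arrays.

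Fewer genes fell. A KDELR2 probe set, for a receptor that returns proteins to the endoplasmic reticulum, was at 411 ± 423 in vivo and at or below background on all 4 in vitro arrays. Its signal was at least 9.22-fold lower in vitro, a bound that became 5.96-fold without in vivo replicate 1 and 14.0-fold without in vivo replicate 4. A second KDELR2 probe set fell by 3.64 on the log2 scale, and another had a log2 fold change of -1.46 at a limma adjusted p of 0.328. The remaining KDELR2 probe set was too dim to be tested, at 17.9 ± 14.9 in vitro and above background on 2 of the in vivo arrays. CH25H, encoding cholesterol 25-hydroxylase, was at 114 ± 29.1 in vivo and fell by 2.46 on the log2 scale. CDK1, the kinase subunit of maturation-promoting factor, fell from 491 ± 231 to 104 ± 41.5 at 1 of 3 tested probe sets, and the others had log2 fold changes of -0.90 and -0.63. AVEN, encoding an inhibitor of apoptosis, fell from 3027 ± 1584 to 832 ± 209. The proton pump subunit gene ATP6V0A4 fell by 1.44 on the log2 scale, as did the zinc finger gene ZBTB45 at 1 of its probe sets, whose others had -0.90 and -0.14. MGMT, which encodes a DNA repair methyltransferase, fell from 973 ± 253 to 419 ± 23.4. The actin nucleation gene ARPC2 fell at 1 probe set with a log2 fold change of -1.09, while its other tested probe sets had 0.20, 0.10 and 0.00. NFIL3, a leucine zipper transcription factor, was at 1084 ± 408 in vivo and 354 ± 88.0 in vitro and did not pass the adjusted threshold (limma adjusted p = 0.0551).

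**Figure D1:**
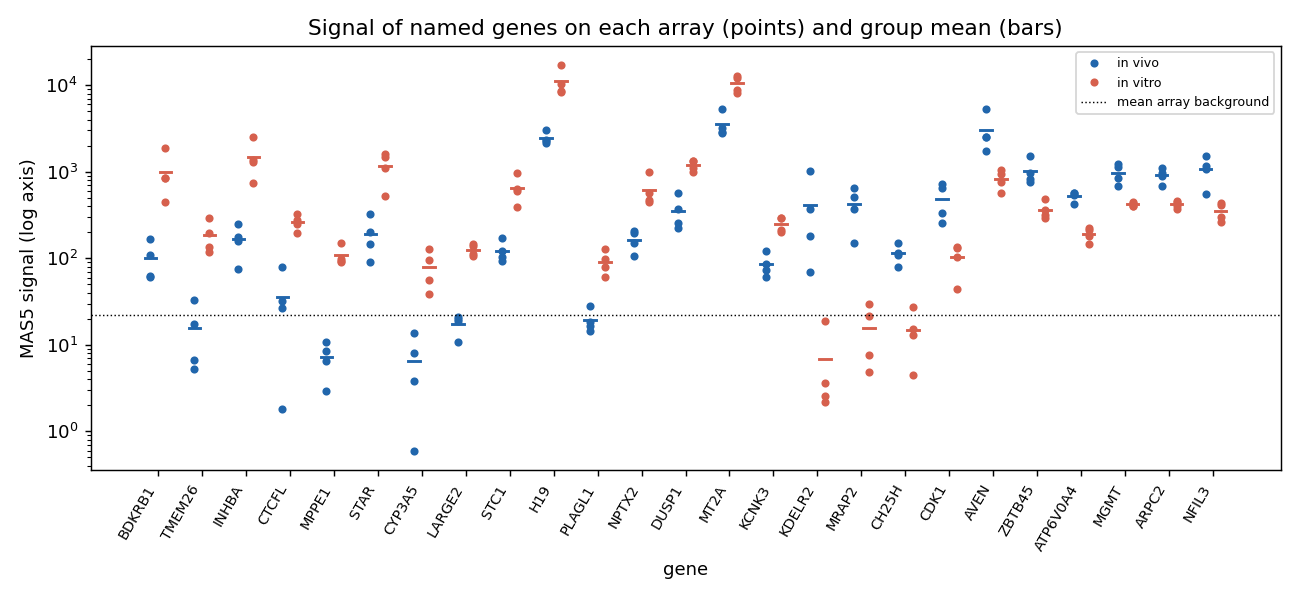
MAS5 signal (log axis) of the genes named by the rule on each array, with a point per array, a bar at each group mean of 4 arrays, and a dotted line at the mean array background. INHBA averaged 165 in vivo and 1483 in vitro, and MRAP2 averaged 423 in vivo and 15.8 in vitro.

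In all, 38 of 26383 tested probe sets passed a limma adjusted p of 0.05, of which 27 were higher and 11 lower in the pools matured in culture. They held 27 distinct named genes, 18 higher and 9 lower, and 8 probe sets with no gene name. MYLIP, TDRD1 and RPL13 rose too, with log2 fold changes of 0.84, 1.36 and 1.38. They lie outside the naming rule and were chosen after their values were seen. RPL13 has many near-identical copies, and its 3 further probe sets had 0.77, 0.29 and 0.16, while the 2 further probe sets of MYLIP had -0.18 and 0.14. At an unadjusted p under 0.05 there were 2700 probe sets, against 1319 on average by chance. The looser rule of an unadjusted p under 0.05 and a 2-fold difference took 693 probe sets, 328 higher and 365 lower. The 4 arrays of a group lay wholly above or below those of the other group at 6.28% of tested probe sets, against 2.86% on average by chance. Neither the 2700 nor the 6.28% was compared with other splits of the arrays. The count of 38 became 71 without in vivo replicate 1 and 97 without in vivo replicate 4, where 45.4% of the calls were higher. It became 18 without in vitro replicate 1, 21 without in vitro replicate 2 and 21 without in vitro replicate 3. The looser count was 1054 without in vivo replicate 4. The ratio of EEF1A1 control signals as a covariate, chosen after seeing the data, gave 292 calls with 122 higher, that of beta-actin gave 65, array weights gave 88, and a fit without the intensity trend gave 10.

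**Figure D2:**
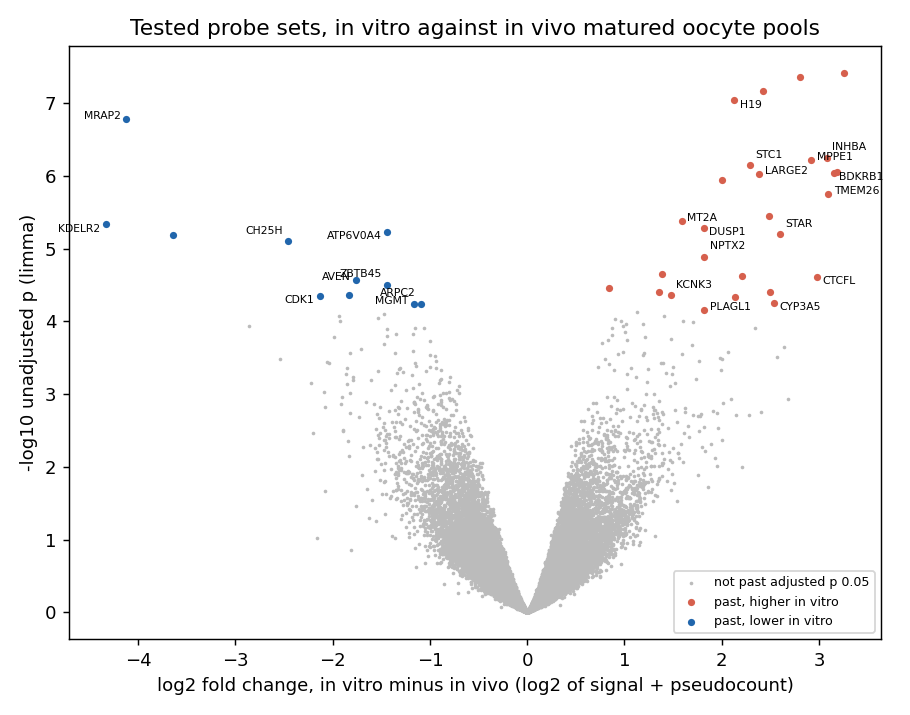
Each point is 1 of 26383 tested probe sets, with the log2 fold change in vitro minus in vivo on the x axis and -log10 of the unadjusted limma p on the y axis. The 27 probe sets past the adjusted threshold and higher in vitro are red, and the 11 lower are blue.

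Of the 24 genes of the naming rule that passed, 9 stayed past the threshold with each array left out in turn: BDKRB1, TMEM26, INHBA, MPPE1, LARGE2, STC1, H19, KDELR2 and MRAP2. Without in vitro replicate 1, 12 of the 23 then tested did not pass, among them STAR, DUSP1, MT2A and CDK1. The corresponding numbers were 10 without in vitro replicate 2, 11 without in vitro replicate 3 and 7 without in vitro replicate 4. They were 1 without in vivo replicate 1, 9 without in vivo replicate 2, 7 without in vivo replicate 3 and 0 without in vivo replicate 4. PLAGL1, KCNK3, CDK1, MGMT and ARPC2 each lost the call with at least 6 of the 8 arrays left out, reaching limma adjusted p-values of 0.213, 0.187, 0.144, 0.167 and 0.186. The highest adjusted p with an array left out was 0.0596 for STAR, 0.0547 for DUSP1, 0.0516 for MT2A, 0.0725 for NPTX2, 0.133 for CTCFL, 0.105 for CYP3A5, 0.0507 for CH25H, 0.139 for AVEN, 0.155 for ZBTB45 and 0.0516 for ATP6V0A4. Without in vivo replicate 4, NFIL3, GGCT and VCAM1 passed with 0.00253, 0.0233 and 0.00607, and without in vivo replicate 1, EFEMP1 and HADHA passed with 0.0161 and 0.0117. Without the intensity trend INHBA, BDKRB1, KDELR2 and STAR had limma adjusted p-values of 0.0508, 0.0574, 0.0932 and 0.134. TMEM26, MPPE1, LARGE2, STC1, H19 and MRAP2 stayed past the threshold under every alternative in which they were tested.

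Genes known as enriched in oocytes did not pass the test. None of 32 tested members rose or fell, and their median log2 fold change was -0.01. MOS, the kinase that holds the egg in metaphase II, was at 4927 ± 478 in vivo and 4944 ± 616 in vitro. The log2 fold change was 0.30 for the oocyte growth factor BMP15, -0.31 for the zona pellucida gene ZP3 and 0.27 for the receptor gene KIT. NLRP5, a maternal effect gene, had -1.03 at a limma adjusted p of 0.204, and it alone passed when p was adjusted over the list alone. NLRP13 had 0.45 and LHX8 had -0.62, and SOHLH1 was at 46.9 ± 23.0 in vivo and 18.2 ± 8.62 in vitro. Among the other genes fixed in advance, the log2 fold change was 0.24 for cyclin B1 (CCNB1), 0.37 for CPEB1, 0.35 for POU5F1, 0.13 for SOD1, -0.28 for HSPA8 and 0.04 for BCL2L10. DNMT1 was too dim to be tested, and GDF9, ZP2 and GJA1 were not analysed here.

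Markers of granulosa and cumulus cells, which surround the oocyte in the follicle, differed in direction from each other. Of 28 tested members, INHBA and STAR rose, 0 fell and 26 did not pass. Adjusted over the list alone, 4 were higher (INHBA, STAR, HSD3B2 and EFEMP1) and 1 was lower (ITIH2). HSD3B2, a steroid dehydrogenase gene, had a log2 fold change of 2.28 and EFEMP1 had 1.96, with limma adjusted p-values of 0.214 and 0.249. The abundant markers SERPINE2, TIMP1, VCAN and VIM had log2 fold changes of -0.13, -0.12, 0.01 and 0.19. The median over the list was -0.07 while its mean was 0.21 and camera's direction was up. Of 15 tested markers of theca, stroma and endothelium, STAR rose, and COL6A1 and TAGLN had 1.77 and 1.82 while DCN had -1.85. Adjusted over the list alone, 3 were higher and 2 lower. Of 9 tested blood and immune markers none passed, and HBB, S100A8 and AIF1 had -1.02, -0.50 and -0.23. CD68, a macrophage marker, was at 49.2 ± 47.2 in vivo and 15.9 ± 7.59 in vitro at its tested probe set.

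Lists of maturation genes changed in few members. Of 48 regulators of meiosis and maturation-promoting factor, CDK1 fell and 47 did not pass, and ARPP19, CDC25B and CCNB3 had log2 fold changes of -0.67, -0.52 and -0.62. None of 47 spindle and kinetochore genes passed, with 0.46 for CDCA8, 0.70 for KNTC1, -0.55 for PCNT and 0.47 for TUBGCP2. None of 60 genes of maternal mRNA storage, polyadenylation and decay passed, with -0.85 for TUT7, 0.58 for TOB2, -0.51 for STAU1 and -0.52 for YBX3. Of 19 imprinted genes, H19 and PLAGL1 rose and 17 did not pass. DLK1 was at 2993 ± 2903 in vivo and 499 ± 191 in vitro (log2 fold change -2.07, limma adjusted p = 0.205), and MEST had 0.50. Adjusted over the list alone, 3 imprinted genes were higher and 1 was lower. None of 55 DNA methylation and chromatin regulators passed, with 0.51 for ASF1B, 0.72 for PRMT1, 0.47 for SUV39H2 and -0.63 for HDAC8. None of 24 pluripotency and early embryo factors passed, with -0.91 for CDX2, -0.81 for MYCL, -0.62 for TEAD4 and 0.33 for TFAP2C. None of 20 histones and histone-like genes passed, with 0.49 for HMGN3, -0.38 for HMGA1, -0.43 for H2AZ1 and -0.89 for H4C8.

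Among stress and metabolic genes, MT2A rose and the other 45 of 46 tested antioxidant genes did not pass. GGCT and SRXN1 had log2 fold changes of 1.19 and 1.08, and GCLC, a glutathione synthesis gene, had -0.64. Adjusted over the list alone, 3 were higher and 1 lower. None of 44 heat shock and unfolded protein response genes passed, with -0.71 for STIP1, -0.62 for BAG1, 0.47 for DNAJA1 and -0.88 for CRYAB. None of 52 nuclear subunits of oxidative phosphorylation passed, and 33 of them had a negative log2 fold change, among them COX7B (-0.80), SDHA (-0.81), NDUFB2 (-0.61) and NDUFS6 (-0.51). COX7B passed when p was adjusted over the list alone. None of 25 glycolysis genes passed, with 0.83 for SLC2A1, 0.73 for LDHA, 0.53 for PDK1 and 0.65 for DLD. None of 19 sterol synthesis genes passed, with -0.64 for NSDHL, -0.49 for MVD, -0.42 for SCAP and 0.45 for PMVK. None of 20 genes of fatty acid oxidation and lipid storage passed, with -1.17 for HADHA, 1.62 for FABP3, -0.41 for ACADVL and -0.49 for ECI1. Adjusted over the list alone, HADHA was lower and FABP3 was higher. The mitochondrially encoded genes were not analysed here, with 0 of 13 named on the array.

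In the remaining lists, none of 32 apoptosis regulators passed, with -0.63 for ENDOG, -1.20 for BIK, -0.64 for BOK and -0.54 for DIABLO. None of 33 ribosomal protein genes passed at its brightest probe set, with 2.10 for RPL24, 0.73 for RPL19, 0.81 for RPS16 and 0.27 for RPL4. RPL24 passed when p was adjusted over the list alone. None of 38 proteasome and ubiquitin genes passed, with -1.47 for UBE2D1, 0.58 for PSMD1, 1.28 for PSMB10 and -0.79 for PSMC5. Adjusted over the list alone, 2 of them were higher and 2 lower. None of 49 DNA repair genes passed, with 0.83 for CLSPN, -0.64 for PARP2, 0.62 for FANCI and 0.47 for CHEK2. None of 42 growth factor and hormone signalling genes passed, with -0.99 for IRS2, 1.22 for PRLR, -0.74 for FGF13 and 0.86 for ERBB3. None of 57 adhesion and matrix genes passed, with -2.08 for VCAM1, -1.31 for LAMB2, -1.27 for HSPG2 and 0.89 for SDC1. None of 41 transporters passed, with 0.87 for SLC1A5, 0.69 for CLCN3 and -0.79 for SLC7A1. SLC1A5, an amino acid transporter gene, passed when p was adjusted over the list alone.

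As sets, 0 of 24 lists passed limma's camera test at an adjusted p of 0.05, the smallest being 0.318, and 2 lists had an unadjusted p under 0.05. These were the DNA methylation and chromatin regulators (up, unadjusted p = 0.0202) and the oxidative phosphorylation subunits (down, unadjusted p = 0.0350). With an estimated correlation 0 lists passed (smallest adjusted p = 0.593), and 0 passed fry's directional test (smallest adjusted p = 0.329). In fry's mixed test, which asks whether members change in either direction, 7 lists passed. Their adjusted p-values ran from 6.27e-06 to 0.0332, and the test does not compare a list with other genes. They were the granulosa and cumulus, imprinted, theca and stroma, antioxidant, fatty acid, growth factor signalling and oxidative phosphorylation lists. The list median was negative and camera's direction up for maternal mRNA, sterol synthesis, DNA repair and transporters, as for granulosa markers. The mean was negative and the median positive for early embryo factors and histones.

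**Figure D3:**
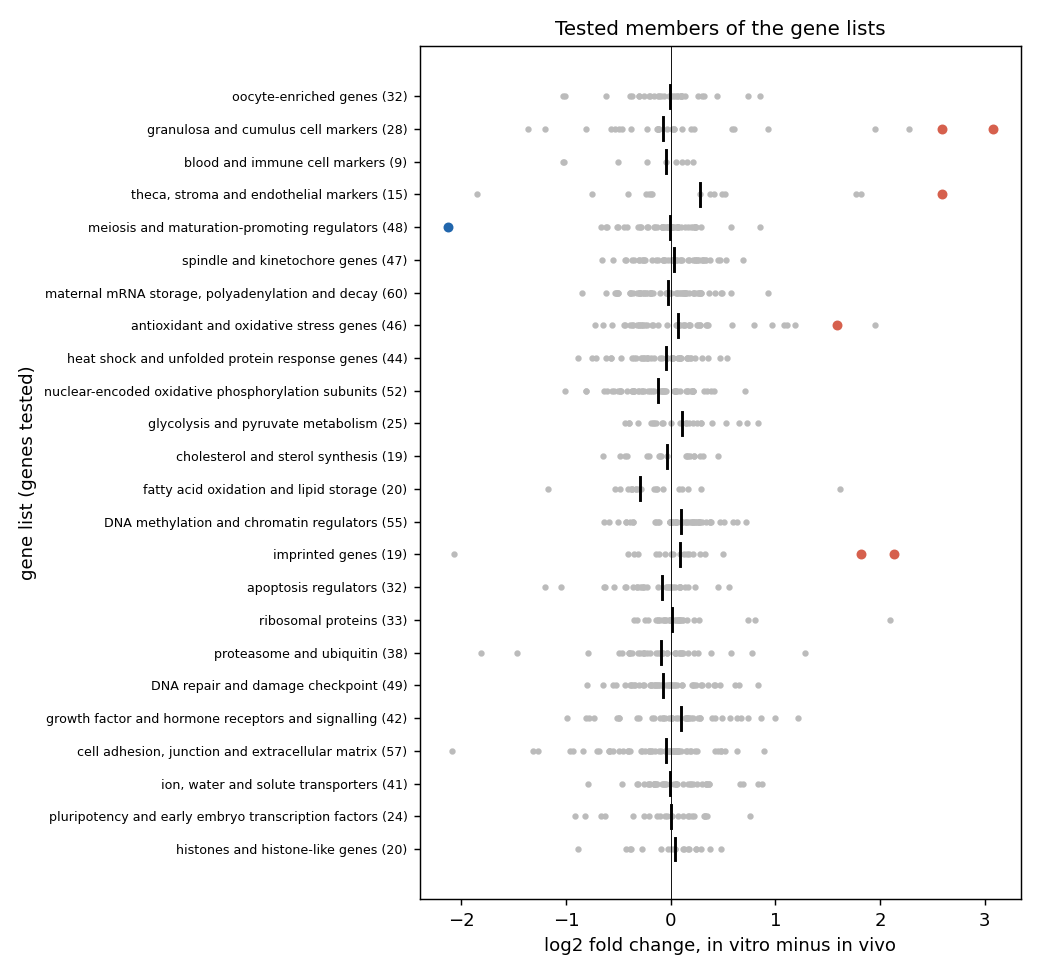
Points are the log2 fold changes, in vitro minus in vivo, of the tested members of each gene list, with 1 probe set per gene, and the black bar is the list median. Members past the adjusted threshold are red when higher and blue when lower, as for INHBA (3.08) and CDK1 (-2.13).

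The second question was how far the groups stood apart. Pearson correlations between arrays were 0.945 to 0.959 within the in vitro group, 0.900 to 0.948 within the in vivo group and 0.915 to 0.952 between groups. The mean distance between groups exceeded that within groups by 0.00769 (exact one-sided permutation p = 0.0286 over 35 splits, the smallest they can give). In vivo replicates 1, 2 and 4 correlated less on average with their own group (0.916, 0.937 and 0.919) than with the in vitro arrays (0.919, 0.947 and 0.932). In vivo replicate 3 (0.924 against 0.921) and every in vitro array correlated more with their own group. The positive difference thus comes from the in vitro group, whose arrays lay close to each other. The exact permutation p of the separation was 0.229 without in vitro replicate 1 and 0.20 without in vitro replicate 2, 3 or 4, and the difference then lay between 0.00261 and 0.00380. The within-group mean then holds a larger share of in vivo pairs, which correlate less, and this alone lowers the difference. These values therefore do not show that the separation rests on any single in vitro array. The first principal component held 25.6% of the variance and parted in vivo replicates 1 and 3 from in vivo replicate 4. The second component held 18.5% and had all in vitro arrays and in vivo replicate 1 at negative scores. The median absolute log2 deviation of an array from its group was 0.383 ± 0.052 in vivo and 0.276 ± 0.015 in vitro (SD, n = 4 each; exact two-sided permutation p = 0.0571). The exact permutation p of this difference was 0.0286 without in vivo replicate 2, where the difference was -0.163. It ran from 0.0571 to 0.171 under the other alternatives, the highest without in vitro replicate 3. With an array left out, deviations in its group are taken from the mean of fewer arrays, which alone enlarges them. The difference was -0.107 with all arrays, -0.112 to -0.163 without an in vivo array and -0.0834 to -0.105 without an in vitro array. These shifts therefore do not show that the difference rests on any single array.

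RNA quality and the reach of the amplification were read from control transcripts. The log2 ratio of 3' to 5' signal of GAPDH was 4.75 ± 0.53 in vivo and 4.98 ± 0.35 in vitro (SD, n = 4 each; exact two-sided permutation p = 0.486). The difference of 0.23 became 0.48 without in vivo replicate 2 (exact permutation p = 0.0571), and it was 0.06 without in vitro replicate 2 and 0.09 without in vivo replicate 3. That of beta-actin was 6.39 ± 0.64 in vivo and 6.18 ± 0.45 in vitro (SD, n = 4 each; exact two-sided permutation p = 0.543). Its difference of -0.21 changed sign, to 0.03, without in vivo replicate 2. The ratio of EEF1A1, examined after seeing the data, was 1.43, 2.94, 1.44 and 3.67 on in vivo replicates 1 to 4 and lay between 1.84 and 2.29 on the in vitro arrays.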

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

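The tests of the EEF1A1 ratio, of array scaling, of the other probe sets of KDELR2 and MRAP2, and of the granulosa markers above background or without INHBA and STAR were chosen after the result was seen. Within groups of 4 arrays, 14 of 258 sets of values had 1 array far from the other 3, where chance gives about 1 in 20 (12.9). In vivo replicate 1 stood apart for COL6A1 (6.8 against 31.0 to 33.9), YBX3 (2873.8 against 1720.6 to 1838.5) and HADHA (588.6 against 981.3 to 1067.7). In vivo replicate 3 stood apart for NSDHL (125.6 against 62.5 to 68.4). In vivo replicate 4 stood apart for ECI1 (63.3 against 77.4 to 79.6) and CHEK2 (270.4 against 423.2 to 426.1). In vitro replicate 1 stood apart for NLRP5 (792.7 against 1220.7 to 1271) and DLD (37.9 against 58.2 to 61.5). In vitro replicate 2 stood apart for MPPE1 (150.5 against 91.7 to 97.3), CD68 (4.7 against 17.9 to 20.6) and YBX3 (1647 against 1302 to 1344.2). In vitro replicate 3 stood apart for PSMD1 (4415.9 against 6335.2 to 6751.4). In vitro replicate 4 stood apart for KDELR2 (18.9 against 2.2 to 3.6) and PMVK (34.7 against 63.4 to 69.0).

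INHBA, STAR and STC1 rose in the pools matured in culture, and INHBA and STAR are abundant in granulosa cells. Carried-over cumulus or granulosa cells would bring all their abundant transcripts, but the median log2 fold change of 20 tested markers with an in vivo signal of at most 500 was -0.08 with an upper 95% bootstrap bound of 0.597, under the limit of 1 set in advance. The 11 of these above background on all arrays had a median of 0.22 with an upper bound of 1.96, but they include INHBA and STAR. Without these genes the upper bound was 0.605 over the 9 left and 0.407 over 18 of the 20. Of the 20, 4 were higher by at least 1 on the log2 scale, INHBA, STAR, HSD3B2 (2.28) and EFEMP1 (1.96), and 16 were not. These values argue against carry-over that raises this set of markers as a whole. They cannot exclude cells that hold only some of the markers, and 9 of the 20 were not above background on all arrays. The 8 brighter markers, led by SERPINE2 with 13703 in vivo and 12488 in vitro, would hide a small share of cells. A difference in the reach of the amplification could not be decided with the EEF1A1 ratio. With that ratio in the fit the smallest log2 fold change of the 3 genes was 2.31. The ratio itself hardly differed between groups, at 2.37 ± 1.12 in vivo and 2.05 ± 0.19 in vitro (SD, exact two-sided permutation p = 0.60). The fit could therefore move the group difference little, whatever its cause. Cells rich in INHBA and STAR but poor in the other markers, and a response of the oocyte to culture, stay open and were not tested.

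KDELR2 and MRAP2 fell to near the floor in the pools matured in culture. A donor variant or a transcript end under a single probe set could give such a drop and would leave other probe sets of the same gene unmoved. For KDELR2 a cause confined to a single probe set is argued against, since its other probe set above background on all 4 in vivo arrays had a log2 fold change of -3.64. The positions of the probe sets were not examined, so a donor variant or transcript end shared by the 2 bright ones stays open. The dimmer KDELR2 probe sets, with -1.46 and -0.37 ± 0.83 (SE), decide nothing. For MRAP2 the number of other probe sets was 0, so there this explanation cannot be told apart from a change in transcript level. An effect of maturation in culture was not tested apart from these.

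The in vivo pools lay farther from each other than the in vitro pools, with a difference in vitro minus in vivo of -0.107 in median absolute log2 deviation (exact two-sided permutation p = 0.0571, which did not pass). Array scaling is argued against, since 82.6% of that difference was left after quantile normalization. It was then -0.0884 (exact two-sided permutation p = 0.143), so it did not pass there either. The 3' to 5' ratio of EEF1A1 followed the first principal component with Pearson's r = 0.74 (exact permutation p = 0.0423, adjusted 0.127 over 3 ratios) and Spearman's rho = 0.64 (exact permutation p = 0.0962, adjusted 0.289) over 8 arrays. Without the 2 farthest arrays, in vivo replicates 2 and 4, r was 0.88. That value mainly sets in vivo replicates 1 and 3 against the in vitro arrays, so it says little about the spread among in vivo arrays. As a covariate the EEF1A1 ratio gave 292 changed probe sets, and 1 of 100 random assignments of the ratio to the arrays gave as many (293), against a median of 30. A varying reach of the amplification is a candidate explanation, mainly from 1 of 3 control ratios. Those of GAPDH and beta-actin gave 32 and 65 calls with r = 0.40 (exact permutation p = 0.326) and 0.45 (exact permutation p = 0.269). Without the 2 farthest arrays of each ratio, their r was 0.60 and 0.73. No biological explanation was tested.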

How the results depend on the processing

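The covariate fits were chosen after seeing the data. All of the 38 called probe sets that were tested kept their direction under each of the 21 alternatives of the fit. The groups of all 38 did not overlap, so only quantile normalization, median centring and the covariate fits could have reversed a direction. The count of changed probe sets was 89 at an adjusted p of 0.10, 10 without the intensity trend, 88 with array weights, 292 with the EEF1A1 ratio and 65 with the beta-actin ratio as a covariate, and 18 to 97 with each array left out. The 38 were all among the 292. With fewer or more probe sets in the test, the looser count was 224 with the upper-quarter filter and 1524 with no filter, and it was 287 with a pseudocount at the median, which shrinks folds of dim probe sets. It ran from 728 to 1054 with each array left out. The cause of the other shifts was not tested. The count of gene lists was 0 by camera under every alternative run and by fry's directional test, run on the main fit only. The lowest adjusted p of these tests was 0.111. Fry's mixed test on the main fit gave 7 lists. Robust eBayes cannot be set in camera and has no value there. The separation of the groups ran from 0.00261 to 0.0147 and the spread difference from -0.163 to -0.0834 with each array left out, with fewer samples in each test. Leaving out an array also changes the weight of each group's pairs in the separation and enlarges the deviations in its own group in the spread. The beta-actin difference ran from -0.464 to 0.0255 with each array left out and was 0.0336 for the 3' over the middle signal, and the cause was not tested. Replicate numbers did not pair the arrays: correlations of deviations of same-numbered arrays were 0.02, -0.01, -0.05 and -0.02, and 1 array of 8 correlated best with its own number. The fit with the replicate number as a block gave 43 calls, 31 of them among the 38. Of 491 values of the 24 called genes under the alternatives, 98 were no longer past the threshold. Dim probe sets near background limit what the arrays can show.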

Other observations

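The test of the EEF1A1 covariate was chosen after the result was seen. With the EEF1A1 ratio in the fit, 18 further named genes passed the adjusted threshold, most of them list members or genes fixed in advance. Their log2 fold changes were -2.45 for VCAM1 and -1.54 for LAMB2, of cell adhesion, -1.14 for IRS2, of insulin signalling, and -2.42 for the imprinted DLK1. HADHA and SDHA, of mitochondrial metabolism, had -1.09 and -0.94. On the other side were HSD3B2 with 2.51, COL6A1 with 1.86 and GGCT with 1.29.

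Unnamed probe sets held the 3 smallest p-values of the comparison. They have no single gene name here, which can mean no symbol, several symbols or only a LOC number. MmugDNA.3343.1.S1_at was at 8.93 ± 4.21 in vivo, not above background on any array, and 152 ± 16.6 in vitro, at least 5.24-fold higher. MmugDNA.39895.1.S1_at was at 77.8 ± 15.1 in vivo and 615 ± 219 in vitro (SD over 4 arrays). The unnamed MmugDNA.18321.1.S1_at was lower in vitro, with 573 ± 294 in vivo and 145 ± 41.9 in vitro.

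A hypothesis was that H19 and PLAGL1 rose because imprinted genes as a whole shifted. The median log2 fold change of the 19 tested imprinted genes was 0.09 with an upper 95% bootstrap bound of 0.216, far below the rise of H19. This argues against a shift of the whole list in a single direction. A median cannot show changes in both directions. Adjusted over the list alone, 3 members were higher and 1 was lower, and fry's mixed test gave an adjusted p of 6.27e-06. The 3 higher include H19 and PLAGL1 themselves, and the mixed test was not run without these genes.

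Other splits of the 8 arrays into groups of 4 were tried. Of 35 splits, 1 gave as many as 38 changed probe sets, the real one, and the highest other gave 0. This argues against a chance split for this count, at the smallest share that 35 splits can give. For the looser rule 1 of 35 splits, the real one, gave as many as 693. The highest other, which parted in vivo replicates 2 and 4 from 1 and 3, gave 645. The rank is again the best that 35 splits allow, but the margin is small, so this count alone does not exclude chance. For gene lists the real count was 0, which all 35 splits reach of necessity (the highest other gave 3), so this count says nothing about chance.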
